A study of Gekko japonicus with 2 samples.

How the data were processed

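Cultured Gekko japonicus blastema cells were given SKL2001 or DMSO and profiled by RNA sequencing, with 1 library per group as the sample titles name them. Per the labels' protocols, cells were kept in DMEM/F12 with serum, RNA was extracted with TRIzol, and libraries were made with a NEBNext Ultra II RNA kit. Nothing in the labels says whether the libraries came from the same animals, and the strand setting of the counting is not given in the sources used here, so reads of overlapping genes cannot be told apart.

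The authors' table gives, per the file headers, a read count per library, an FPKM value and a length for each gene. The tools named are fastp 0.22.0, HISAT2 2.1.0, HTSeq 0.9.1 and DESeq 1.38.3, per the submitters' processing notes, which give them here without role or order. Deposited counts are whole numbers and were not normalized. Deposited FPKM values equalled the count divided by gene length and by the library's total count, to within 0.01% for each of the 16153 and 16306 genes with a read, and were 0 for the others. The genome build is not given in the sources used here, but all 19476 genes matched a RefSeq gene table of the assembly Gekko_japonicus_V1.1 by symbol, and 19476 had the same start and end. Coordinates are those of the deposited table. The table also holds 49 lines of overflowing annotation text without values, which were left out, and 21 symbols turned into dates in its name column, for which the gene identifier was used. There were 0 duplicated symbols and 0 columns of values that matched no sample.

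The DMSO library had 12805881 reads in genes and 16153 genes with a read, and the SKL2001 library had 10980868 reads and 16306 genes, with 2494 genes at 0 in both. In a gene of 1 kb, 3 reads correspond to 0.234 FPKM in the DMSO library and 0.273 in the SKL2001 library. The 20 genes with most reads took 12.1% of reads in the DMSO library and 15.1% in the SKL2001 library. The sum of FPKM over genes was 515174 in the DMSO library and 585465 in the SKL2001 library, and the median FPKM was 5.00 and 3.47. Across the 13163 measured genes, which are not independent replicates, log2(FPKM + 1) had a Spearman correlation of 0.891 and a Pearson correlation of 0.898 between the libraries.

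Groups, comparisons, alternatives, gene lists and the rule for named genes were set before the data were examined, except where stated. The design foresaw FPKM alone; the table also held counts, and these gave the counting intervals. No test between conditions was run, since each group had 1 library. Genes with an FPKM of at least 1 in either library entered, the log2 ratio was taken of FPKM + 1, and a log2 ratio of 1 or more in either direction counted as a difference. Such a ratio understates differences of low genes. Folds of named genes are ratios of FPKM without the added 1, with an exact conditional binomial 95% interval (Clopper-Pearson) from the counts of both libraries. Where the DMSO library had 0 reads, the fold was taken against a floor of 3 reads per library, and no fold is given where both libraries were at or near the floor. With 1 to 3 reads the ratio stands with its interval, which is wide. In all, 3099 of the 3111 genes that differed at least 2-fold had an interval that excluded a fold of 1. Those genes were selected for a difference in the same counts, so this adds little support to their calls.

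The 37 gene lists covered Wnt, FGF, adhesion, migration, cell cycle, other signalling, stress, metabolism and markers of other cell types. Of their 1053 symbols, 889 were in the table. Lists with at least 5 measured members, 34 in all, were compared with 10000 random lists of the same size matched on mean log2 level in 20 bins, and a list stood apart below percentile 2.5 or above percentile 97.5. Named genes were FGF20 and Wnt genes, 14 in all, the 10 highest and 10 lowest ratios among genes with a symbol, the 2 most different members of each list with up to 2 abundant ones, and the 5 genes with the largest FPKM difference in each direction. Of 191 genes named or eligible, 10 overlapped another gene of the table. Not every gene that the rule selects is reported here.

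The alternatives were other pseudocounts (0.1 and 0.5), other filters on low values, scaling to equal FPKM totals, by the median ratio or by a trimmed mean, removal of the 20 most abundant genes before the totals were made equal, 10 bins in place of 20, list means, and lists without their most extreme member. Chosen after the values were seen were removal of the 13 mitochondrial genes before the FPKM totals were made equal, removal of their reads from the library totals, matching on gene length, removal of the trend with length, random lists of genes with a symbol, and KEGG pathways from the table's annotation. The methods were tested on simulated counts for all 19476 genes of the SKL2001 against DMSO comparison. The genes given a known fold were drawn from those with an FPKM of at least 5, so calls of lower genes were not tried. Of 50 such genes each at 3-fold, 4-fold and 8-fold, 100% were called in the true direction and 0% in the wrong one. At 1.5-fold 0% were called. The intervals covered the true fold for 92% to 96% of these genes. Of 100 simulated lists of 25 unchanged genes, 8 lay outside the central 95%. All 100 of 100 lists shifted by 1 on the log2 scale lay above percentile 97.5. Members were drawn at random, with independent noise added to each ratio, so lists whose members vary together were not tried. Smaller lists and smaller shifts were not tried either. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.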

Results

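RNA sequencing was used to compare cultured blastema cells of the gecko Gekko japonicus given SKL2001 with cells given DMSO. The blastema is the mass of progenitor cells that forms at the wound of a lost tail and rebuilds it. SKL2001 is a small molecule that activates canonical Wnt signalling by freeing beta-catenin from Axin, and DMSO is the solvent that serves as the negative control. Each group held 1 library, with 12805881 reads assigned to genes in the DMSO library and 10980868 in the SKL2001 library. The labels give neither the dose nor the length of exposure. The title of the series names a Wnt and FGF20 axis in the migration of proximal blastema cells, and Wnt, FGF and migration genes are described in turn.

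With 1 library per group, no difference below has a replicate check, and no test between conditions was possible. Values are FPKM (reads per kilobase of gene, scaled by the reads assigned in the library), and a fold is the ratio of FPKM between the libraries. The range after a fold is its exact 95% conditional binomial interval. With 1 library per group that interval covers counting error only. It may be too narrow even for that, since reads without molecular identifiers are not independent molecules. A gene counts as higher or lower in the SKL2001 library when its ratio of FPKM + 1 reaches 2-fold, among the 13163 genes with an FPKM of at least 1 in either library. For each gene list, the median log2 ratio is given with its percentile among 10000 random lists matched on expression, which describes these 2 libraries and is not a test of the treatment.

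The SKL2001 library had 973 genes at least 2-fold higher and 2138 at least 2-fold lower, together 23.6% of the measured genes. At least 4-fold differences were seen in 77 higher and 267 lower genes. Reads redrawn with no difference between the libraries gave 5 higher and 4 lower genes, a value for counting noise alone, since the spread between separate cultures was not measured. The median log2 ratio of all measured genes was -0.14, with quartiles of -0.73 and 0.41, and list medians are to be read relative to that shift. Scaling by the median ratio moved the median of all genes to -0.02 and the split to 1297 higher and 1799 lower, and the trimmed mean moved it to -0.01 and the split to 1349 and 1760. Scaling both libraries to the same FPKM total moved the median the other way, to -0.31, and the split to 884 higher and 3210 lower. That total was above the FPKM sum of either library, so FPKM values rose while the added 1 and the filter stayed. It measured 14150 genes in place of 13163, so counts at equal FPKM totals, those of lists included, do not show scaling alone. With a pseudocount of 0.5 and no scaling, the median was -0.15 and the split 1169 higher and 2516 lower. Genes higher made up 31.3% of the differing genes in the values as deposited, 41.9% after the median ratio, 43.4% after the trimmed mean and 21.6% at equal FPKM totals.

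Targets of canonical Wnt signalling went both ways, with 7 of 25 measured members of the list higher in the SKL2001 library, 5 lower and 13 neither. The list median was -0.13, at percentile 45.5 of the matched random lists, while the mean was 0.25 at percentile 99.35, so the median and mean differ in sign. After the median-ratio and trimmed-mean scalings 3 members were lower, without CCND1 and FZD7. APCDD1, a membrane inhibitor of Wnt ligands, had 3.52 FPKM in the DMSO library and 52.1 in the SKL2001 library, 14.8-fold higher (12.1 to 18.2). AXIN2, the negative feedback scaffold of the beta-catenin destruction complex, was 7.82-fold higher (6.88 to 8.93), with 4.33 and 33.9 FPKM. LEF1, a transcription factor that partners beta-catenin, was 4.75-fold higher (4.26 to 5.31). NOTUM, which removes the lipid of Wnt ligands, was 4.21-fold higher (3.51 to 5.06), and ZNRF3, a ligase that removes Wnt receptors, was 2.73-fold higher (2.37 to 3.15). NKD1, a further feedback inhibitor, was 1.91-fold higher (1.58 to 2.31), short of the 2-fold limit. DKK4, a secreted inhibitor chosen after its values were seen, had 4 and 26 reads and was 7.58-fold higher (2.63 to 29.9).

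Among the lower Wnt targets, the secreted inhibitor DKK1 was 2.92-fold lower (2.19 to 3.94) and CCND1, which encodes cyclin D1, was 2.15-fold lower (1.98 to 2.35). The others were chosen after their values were seen: T, the brachyury gene, was 5.40-fold lower (2.75 to 11.8), WISP1, a matricellular gene, was 4.47-fold lower (3.64 to 5.54), and the receptor gene FZD7 was 2.09-fold lower (1.85 to 2.37). CCND1 and FZD7 lie close to the limit, with log2 ratios of FPKM + 1 of -1.08 and -1.01 as deposited, -0.96 and -0.89 after the median ratio, and -0.94 and -0.87 after the trimmed mean. MYC, a further target, had 46.1 and 37.9 FPKM, and CTNNB1, the gene of beta-catenin itself, had 258 and 215, both within the 2-fold limit. LGR5 had 2 reads in the DMSO library and 4 in the SKL2001 library, and SP5 had 0 in both, too few for a difference to be detectable at this depth. No gene of the table carried the symbol RNF43. A filter at an FPKM of at least 5 in either library took out T and, among the higher targets, DKK4. Of the 14 Wnt and FGF20 genes chosen for naming, 13 had a row and 10 were measured, 5 of them higher and 2 lower. In coordinates of the deposited table, APCDD1 spans 221294 to 262914 on scaffold NW_015163096.1 and AXIN2 spans 539360 to 589269 on NW_015162491.1.

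**Figure D1:**
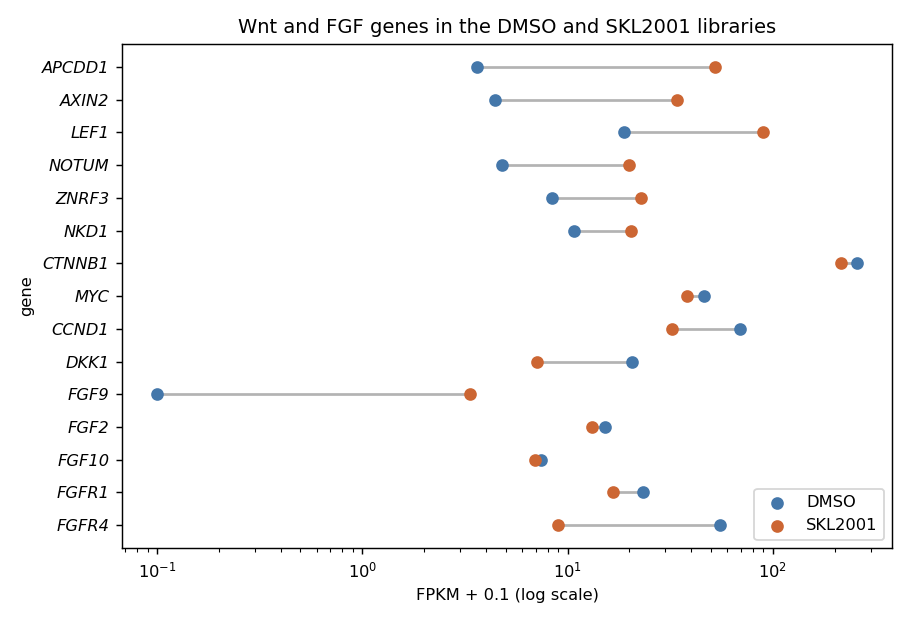
Wnt and FGF genes in the DMSO library (blue points) and the SKL2001 library (orange points), 1 library each, on a log axis of FPKM + 0.1. APCDD1 lay at 3.52 and 52.1 FPKM and FGFR4 at 55 and 8.86; of the FGF genes drawn, FGF2 and FGF10 were chosen after their values were seen.

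The Wnt target BAMBI, a decoy receptor that dampens BMP and TGF-beta signalling, was 2.96-fold higher (2.76 to 3.19), and MSX2 had 229 and 240 FPKM. Among Wnt ligands, receptors, other pathway components and secreted inhibitors, 3 of 39 were higher, 9 were lower and 27 were neither. The median of this mixed list was -0.27 at percentile 27.5. The Wnt amplifier RSPO3 was 14.4-fold lower (5.36 to 54.2), from 67 reads in the DMSO library to 4, and the ligand gene WNT1 was 10.0-fold lower (4.66 to 25.8). The higher members, chosen after their values were seen, were the ligand genes WNT10A, from 4 reads to 33 and 9.62-fold higher (3.42 to 37.4), and WNT7A, from 6 to 41 and 7.97-fold higher (3.36 to 23.0), and AXIN1, 2.18-fold higher (1.96 to 2.42). AXIN1 fell short of the limit at equal FPKM totals, with a log2 ratio of 0.92 in place of 1.08. A filter at an FPKM of at least 5 in either library took out WNT10A and WNT7A, and the lower FZD4. WLS, which carries Wnt ligands to the cell surface, had 154 and 104 FPKM.

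FGF20, the growth factor of the series title, had 0 reads in the DMSO library and 1 read in the SKL2001 library. The floor of 3 reads corresponds to 0.363 FPKM for FGF20 in the DMSO library and 0.424 in the SKL2001 library, so a difference was not detectable at this depth. The table gives FGF20 a length of 645 bases, and whether that gene model is complete is not given in the sources used here, so reads from parts it lacks would be missed. FGF9, a close relative of FGF20, had 0 and 23 reads and was at least 8.94-fold higher in the SKL2001 library against the floor of 3 reads per library, with a counting interval that starts at 6.70-fold. The receptor gene FGFR4 was 6.20-fold lower (5.53 to 6.98), with 55 and 8.86 FPKM, and FGFR1 was 1.41-fold lower (1.28 to 1.56). Of 14 measured FGF ligands and receptors, 4 were higher, 3 were lower and 7 were neither. Their median of -0.03 lay at percentile 73.3 and turned to 0.06 and 0.07 after the median-ratio and trimmed-mean scalings and to 0.02 with mitochondrial reads left out of the totals. The 3 members at 0 reads lie above that median with or without the floor, so the floor cannot move it. Further FGF genes were chosen after their values were seen. FGF8 had 0 and 8 reads and was at least 3.11-fold higher against that floor, and FGF18 had 0 and 9 reads and was at least 3.50-fold higher, with counting intervals that start at 1.99-fold and 2.30-fold, and FGF19 was 2.75-fold higher (1.43 to 5.56). FGF13 had 26 and 1 reads and was 22.3-fold lower (3.66 to 914), and FGFRL1 was 2.44-fold lower (2.03 to 2.96). A filter at an FPKM of at least 5 in either library took out FGF8, FGF9, FGF18 and FGF19, the higher members, and FGF13. A filter at a mean FPKM of at least 1 took out FGF8, FGF13 and FGF18. With mitochondrial genes removed before the FPKM totals were made equal, FGF19 fell just short of the limit, with a log2 ratio of 0.999 in place of 1.06. FGF16 had 5 and 4 reads, FGF2 had 15.1 and 13 FPKM, and FGF10 had 7.33 and 6.85.

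Genes induced by FGF and ERK signalling went both ways. Of 22 measured, 2 were higher, 4 were lower and 16 were neither, with a median of -0.19 at percentile 18.9. ETV1, an ETS transcription factor, was 9.88-fold lower (6.56 to 15.5), and the feedback inhibitor SPRY2 was 5.33-fold lower (4.63 to 6.16). JUN, an AP-1 subunit, was 3.11-fold higher (2.95 to 3.28), and HBEGF had 87.8 and 104 FPKM.

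Lists of cell adhesion and movement genes lay below matched random lists. Of 31 integrins and focal adhesion proteins, 13 were lower, 0 higher and 18 neither, and their median of -0.82 lay at percentile 0. The laminin receptor subunit ITGA6 was 6.47-fold lower (5.97 to 7.03), and TNS1, which links integrins to actin, was 7.23-fold lower (5.43 to 9.81). ITGB1 had 391 and 363 FPKM and ACTN4 had 219 and 142. Of 35 genes of actin regulation and cell motility, 9 were lower, 0 higher and 26 neither, with a median of -0.39 at percentile 0.05. ACTR2, a subunit of the ARP2/3 complex that branches actin filaments, was 3.68-fold lower (3.35 to 4.06), and the formin DIAPH3 was 5.24-fold lower (4.41 to 6.25). CFL1 had 667 and 718 FPKM and TAGLN had 2261 and 2453.

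Of 14 genes of the epithelial-mesenchymal transition, 2 were lower, 0 higher and 12 neither, with a median of -0.71 at percentile 0.31. At equal FPKM totals 4 were lower. The list holds mesenchymal and epithelial genes together, so its median does not give the direction of a transition. The lower genes in the deposited values were SNAI2, a repressor of epithelial genes, 4.07-fold lower (3.69 to 4.49), and TJP1, a tight junction scaffold, 2.92-fold lower (2.68 to 3.17). VIM had 1324 and 965 FPKM. Of 28 matrix proteases and inhibitors, 1 was higher, 9 were lower and 18 were neither, with a median of -0.52 at percentile 0.39. ADAMTS4 was 6.50-fold lower (5.58 to 7.60), while MMP9 had 429 and 444 FPKM and MMP14 had 308 and 353. Of 38 extracellular matrix genes, 10 were lower and 0 higher, with a median of -0.37 at percentile 0.80, or 5.25 when random lists were matched on gene length as well. FBLN2 and LOXL1 were 3.40-fold and 2.91-fold lower, FN1 was 1.69-fold lower, and SPARC had 1331 and 1515 FPKM.

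Genes tied to blastema and limb or tail bud progenitors had 5 of 23 lower and 0 higher, with a median of -0.41 at percentile 11.7. The growth regulators HMGA2 and IGF2BP1 were 2.91-fold and 3.65-fold lower, and the matrix protein TNC was 2.08-fold lower (2.03 to 2.13). TNC lay close to the limit, with a log2 ratio of FPKM + 1 of -1.05 as deposited. It was -0.92 after the median ratio, -0.91 after the trimmed mean and -0.98 with mitochondrial reads left out of the totals. In each of these settings the list had 4 members lower and 1 higher.

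The lowest medians of the 34 lists were in the cell cycle. All 30 DNA replication genes had lower values in the SKL2001 library, here and under each scaling alternative, 20 of them at least 2-fold, with a median of -1.74 at percentile 0. MCM3, a subunit of the replicative helicase, was 8.95-fold lower (6.38 to 12.9). CCNE2, a cyclin of S phase entry, was 9.04-fold lower (6.04 to 14.1), RRM2 was 4.15-fold lower and PCNA, the sliding clamp, was 1.98-fold lower. Of 27 G2 and mitosis genes, 24 were lower and 0 higher, with a median of -1.90 at percentile 0. TOP2A, the topoisomerase that separates chromosomes, was 10.6-fold lower (8.84 to 12.9), with 40.0 and 3.76 FPKM. ANLN was 5.62-fold lower, CCNB1 was 4.52-fold lower, and the mitotic kinase gene PLK1 was 4.77-fold lower. PLK1 overlaps DCTN5 on the same strand, so reads from the shared part are uncertain.

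**Figure D2:**
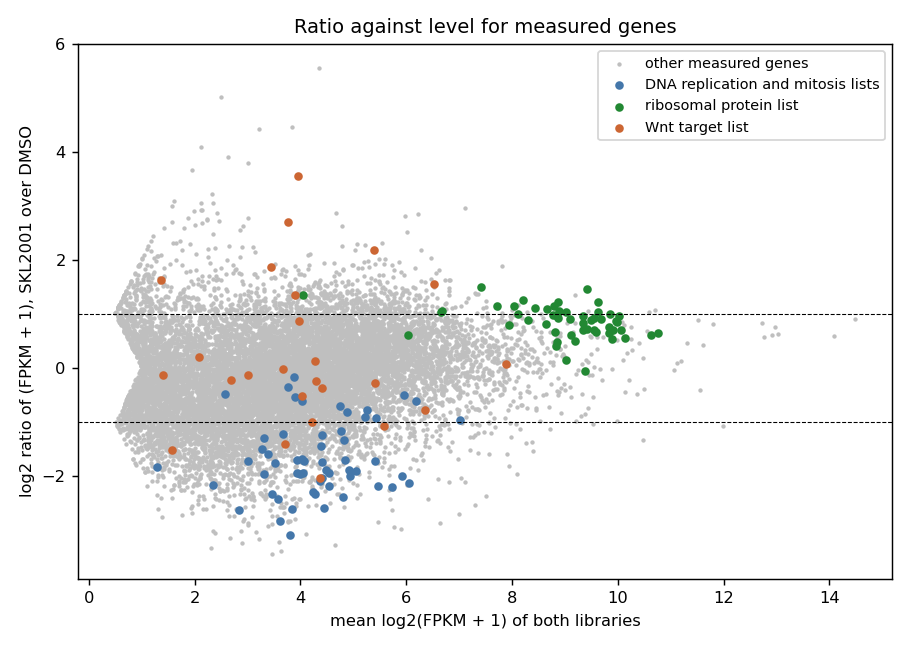
Log2 ratio of FPKM + 1, SKL2001 over DMSO, against the mean log2 level of both libraries, 1 point per measured gene; dashed lines mark log2 ratios of 1 and -1. Of the 57 DNA replication and mitosis genes (blue), 44 lie at or below the lower line, 16 of 53 ribosomal protein genes (green) lie at or above the upper line, and Wnt targets (orange) lie on both sides.

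Targets of YAP and TEAD, transcription regulators that respond to cell density and tension, had 7 of 13 lower and 0 higher, with a median of -1.28 at percentile 0. AMOTL1 was 4.18-fold lower, MYOF was 3.45-fold lower, and the matricellular genes CTGF and CYR61 were 2.45-fold and 1.68-fold lower. BMP and TGF-beta genes had 6 of 27 lower and 0 higher, with a median of -0.58 at percentile 0.81. FST, an activin antagonist, was 5.53-fold lower (5.16 to 5.94). That list lay inside the central 95% after the median-ratio and trimmed-mean scalings, at percentiles 2.63 and 2.75. Notch genes had 4 of 11 lower and 0 higher, with a median of -0.41 at percentile 25, while the mean of -0.88 lay at percentile 0.71. NOTCH3 was 7.86-fold lower (7.07 to 8.75), the ligand gene JAG2 was 7.14-fold lower and HES4 was 4.09-fold lower, while JAG1 had 23.2 and 17.6 FPKM. Hedgehog genes had 2 of 10 higher and 4 lower, with a median of -0.92 at percentile 0.61, or 2.51 without the most extreme member, and a mean of -0.53 at percentile 7.09; at equal FPKM totals 7 of 11 were lower. The transcription factor genes GLI3 and GLI2 were 3.42-fold and 2.36-fold lower, DHH was 15.9-fold lower (4.09 to 136) from 37 reads to 2, and GAS1 was 2.68-fold higher.

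Stress genes were divided. Of 20 p53 and apoptosis genes, 8 were higher, 1 was lower and 11 were neither, with a median of 0.09 at percentile 69.8 that turned to -0.09 when scaled to equal FPKM totals. The mean of this list was 0.47, at percentile 99.88, and 3 members were lower at equal FPKM totals. CDKN1A, which encodes the cell cycle inhibitor p21, was 7.98-fold higher (7.64 to 8.34), with 48.4 and 386 FPKM. GADD45G was 8.04-fold higher (6.71 to 9.71), and MDM2, the ligase that degrades p53, was 2.62-fold higher (2.49 to 2.75). Unfolded protein and integrated stress response genes had 4 of 22 higher and 3 lower, with a median of 0.15 at percentile 70.5, which turned to -0.01 at equal FPKM totals. CHAC1 was 22.2-fold higher (11 to 52.3) and DDIT3, which encodes CHOP, was 4.18-fold higher (3.75 to 4.66), while the chaperone genes HSPA5 and HSP90B1 were 2.61-fold and 1.40-fold lower. NRF2 targets had 2 of 17 higher and 1 lower, with a median of 0.07 at percentile 63.4 that was negative at equal FPKM totals (-0.11) and when the mitochondrial or the 20 most abundant genes were removed before the totals were made equal (both -0.01). HMOX1, the haem-degrading enzyme, was 5.93-fold higher (5.41 to 6.51) and SRXN1 was 2.97-fold higher, while PRDX1 was 1.42-fold lower and FTH1 had 164 and 173 FPKM. Heat shock genes had 2 of 13 lower and 0 higher, with a median of -0.45 at percentile 1.77, or 11.9 without the most extreme member and 3.19 with matching on length. HSPB8 was 3.74-fold lower, HSP90AA1 was 2.63-fold lower, HSP90AB1 was 1.33-fold higher and HSPD1 had 337 and 368 FPKM.

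Cytosolic ribosomal protein genes were higher together. Of 53 measured, 16 were at least 2-fold higher, 0 were lower and 52 had a higher value, with a median of 0.89 at percentile 100. The number at least 2-fold higher was 6 at equal FPKM totals, 28 after the median ratio and 29 after the trimmed mean; the first and last had medians of 0.71 and 1.04. The most different were RPL34, 2.85-fold higher (2.61 to 3.12), and RPS12, 2.75-fold higher (2.63 to 2.88), and the abundant RPLP0 and RPS2 were 1.52-fold and 1.56-fold higher. Ribosomal protein genes are short and have near-identical copies, so single members are uncertain. Nuclear genes of the respiratory chain had 1 of 25 higher and 0 lower, with a median of 0.15 at percentile 52.1, which turned to -0.03 at equal FPKM totals; NDUFB3 was 2.16-fold higher. The 13 genes encoded in the mitochondrial genome took 7.26% of reads (7.25 to 7.28, Clopper-Pearson 95%) in the DMSO library and 11.6% (11.58 to 11.62) in the SKL2001 library. Of these genes, 12 had more than 3 reads in the DMSO library and were 1.25-fold to 2.11-fold higher.

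Glycolysis and hypoxia genes had 9 of 23 lower and 0 higher, with a median of -0.74 at percentile 0. NDRG1 was 8.09-fold lower (7.20 to 9.13) and EGLN3, an oxygen-sensing hydroxylase, was 4.99-fold lower, while PKM and GAPDH were 1.18-fold and 1.32-fold lower. Sterol synthesis genes had 1 of 22 higher and 0 lower, with a median of -0.09 at percentile 36.1 that turned to 0.02 and 0.04 after the median-ratio and trimmed-mean scalings, and 4 were lower at equal FPKM totals; LSS was 2.61-fold higher. Inflammation genes had 2 of 13 lower and 0 higher, with a median of -0.10 at percentile 58.9 that turned to 0.00487 and 0.02 after the same scalings. The adhesion receptor gene VCAM1 was 8.69-fold lower (6.35 to 12.2), and TLR2 was 29.2-fold lower (7.77 to 246) with 2 reads in the SKL2001 library. Interferon response genes had 2 of 9 lower and 0 higher, with a median of -0.54 at percentile 20.9; STAT2 and DHX58 were 5.46-fold and 3.06-fold lower, and 1 member was lower after the median-ratio and trimmed-mean scalings. Spliceosome genes had 2 of 28 lower and 0 higher, with a median of 0.05 at percentile 15.5 that turned to -0.13 at equal FPKM totals and to -0.03 and -0.02 when the mitochondrial or the 20 most abundant genes were removed before the totals were made equal. At equal FPKM totals 6 were lower, with either of those removals 4 were, and after the median ratio or trimmed mean 1 was. HNRNPA1 and SRSF3 were 2.33-fold and 2.06-fold lower.

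**Figure D3:**
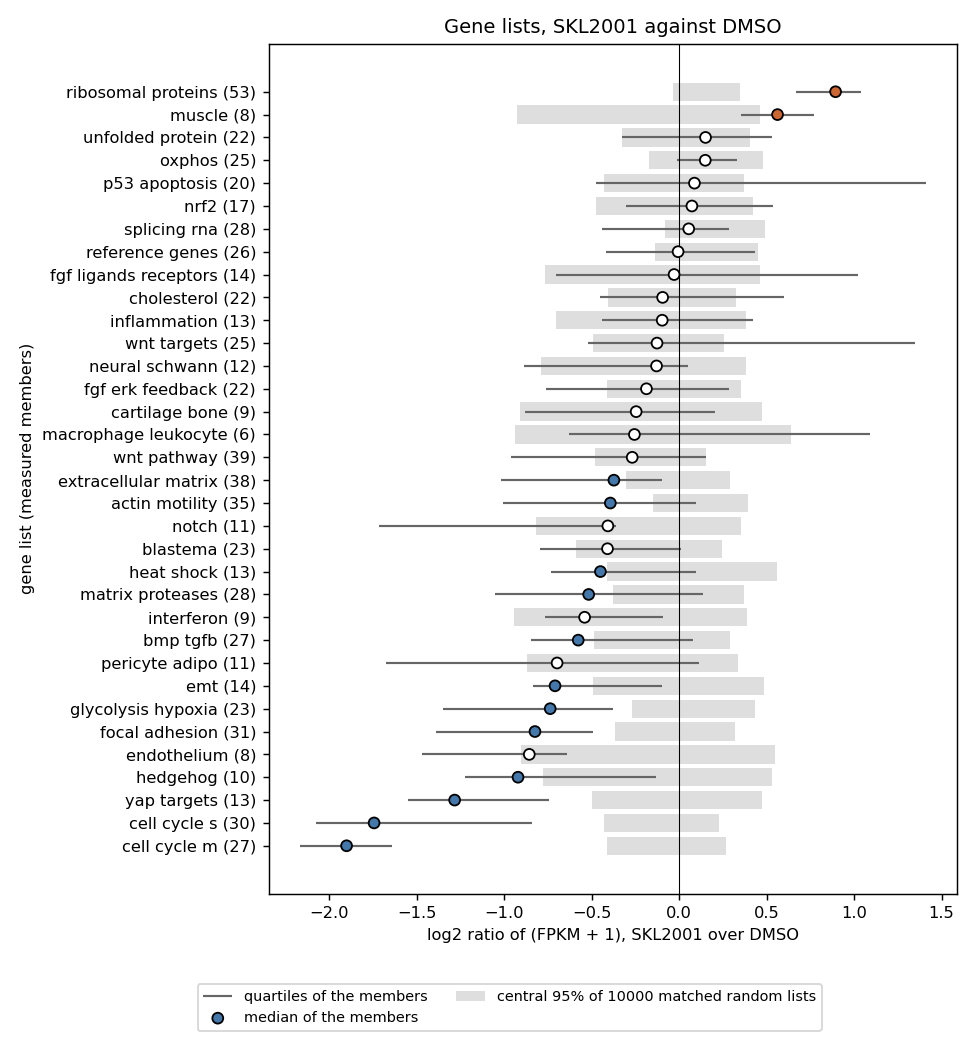
Median log2 ratio of FPKM + 1, SKL2001 over DMSO, for the 34 gene lists with at least 5 measured members (points), the quartiles of the members (lines) and the central 95% of 10000 matched random lists (grey bars); filled points lie outside the bars. The mitosis list has the lowest median, -1.90, and the ribosomal protein list the highest, 0.89.

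Skeletal muscle genes had 1 of 8 higher and 1 lower, with a median of 0.56 at percentile 98.7, or 96.6 without the most extreme member and 93.1 with no filter on low values. TNNC1 was 13.8-fold higher (8.12 to 25.1), from 15 to 177 reads, ACTA1 was 3.33-fold lower, and PAX3 was 1.70-fold higher. Macrophage and leukocyte genes had 2 of 6 higher and 1 lower, with a median of -0.26 at percentile 44.6. CD74 was 9.72-fold higher (5.32 to 19.4), TYROBP had 0 and 20 reads and was at least 7.77-fold higher against the floor (counting interval from 5.76-fold), ITGB2 was 3.02-fold lower and CD68 had 143 and 108 FPKM. Endothelial genes had 3 of 8 lower and 0 higher, with a median of -0.86 at percentile 3.71, or -1.53 at percentile 0.90 with a pseudocount of 0.1 and a mean of -1.10 at percentile 0.13, and 5 of 12 lower at equal FPKM totals; APLNR was 15.8-fold lower (9.57 to 28.0) and ROBO4 5.70-fold lower. Pericyte and adipocyte genes had 1 of 11 higher and 4 lower, with a median of -0.70 at percentile 8.45, or -1.65 at percentile 0.14 with an FPKM of at least 5, -0.61 at percentile 1.69 with no filter and a mean of -0.77 at percentile 2.23; CIDEC was 5.22-fold lower and MCAM 3.31-fold lower. Neural and Schwann cell genes had 3 of 12 lower and 0 higher, with a median of -0.13 at percentile 61.9; NGFR was 11-fold lower (6.71 to 19.2) and PMP22 3.24-fold lower. Cartilage and bone genes had 2 of 9 lower and 0 higher, with a median of -0.25 at percentile 49.3, and 5 of 15 lower and 2 higher at equal FPKM totals; HAPLN1 and RUNX3 were 3.46-fold and 3.43-fold lower.

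Epidermal, erythroid and histone lists had 4, 2 and 2 measured members, too few for a percentile. TP63, a regulator of epidermal cells, was 15.5-fold lower (7.98 to 34.6), from 163 to 9 reads, while EPCAM had 13.7 and 13.8 FPKM. Of the erythroid genes, TFRC had 152 and 135 FPKM and ALAS2 had 1.15 and 2.05, and of the histone genes, H3F3A had 305 and 379 FPKM and H3F3B had 366 and 227. Genes often used as expression references had 1 of 26 higher and 3 lower, with a median of -0.01 at percentile 14.2 that turned to 0.12 and 0.13 after the median-ratio and trimmed-mean scalings and to 0.06 with mitochondrial reads left out of the totals. Members higher then numbered 4 after either scaling and 3 with those reads left out. TBP was 3.07-fold higher, TUBA1B was 3.04-fold lower and EEF1A1 had 2151 and 2289 FPKM. In all, 2 of 34 lists stood above and 12 below the central 95% of random lists, where 1.7 would by chance.

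Among genes with a symbol, the 10 highest ratios included TNFRSF11B, which encodes the decoy receptor osteoprotegerin, with 1 read in the DMSO library and 244 in the SKL2001 library, 285-fold higher (50.6 to 11285). AMDHD1 had 1 and 140 reads, 163-fold higher (28.8 to 6494), and TCTEX1D4 had 1 and 116 reads, 135-fold higher (23.8 to 5389). CCNB1IP1 was 32.2-fold higher (21.1 to 51.8), MBLAC1 38.5-fold (16.2 to 120), MYOZ3 22.7-fold (10.7 to 57.4), KCNMB4 18.9-fold (7.77 to 59.7) and SLC3A1 17.8-fold (11.3 to 29.5), and APCDD1 and CDKN1A completed the 10. MBLAC1 overlaps an unnamed gene on the same strand. The 10 lowest ratios held TOP2A and APLNR together with BARX2, a homeobox gene, 15.4-fold lower (11 to 22.1), and SPATS2L, 13.9-fold lower (11.2 to 17.6). CKAP2L, a spindle protein gene that overlaps NT5DC4 on the opposite strand, was 26.1-fold lower (15.6 to 47.0). DHRS3, which reduces retinal, was 11-fold lower (9.58 to 12.7), DAB2 12.2-fold (10.1 to 14.7), EML4 12.8-fold (9.75 to 17.2), CDR2L 15.6-fold (10.1 to 25.1) and SEMA3F 17.5-fold (11.3 to 28.5).

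By FPKM difference, the 5 genes with the largest excess in the SKL2001 library were the mitochondrial COX3, COX1, COX2, ATP6 and ND4, 1.88-fold, 1.51-fold, 1.68-fold, 1.78-fold and 1.55-fold higher. In the DMSO library the largest excess was in ACTG1, a cytoplasmic actin, with 2280 and 895 FPKM, 2.55-fold lower in the SKL2001 library (2.51 to 2.58). TMSB4X, EIF4A1, ENO1 and TUBB followed, 1.33-fold, 1.98-fold, 2.06-fold and 1.99-fold lower. Actins and tubulins have near-identical relatives, and how reads were divided among them is not given in the sources used here.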

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

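Matching on gene length, removal of mitochondrial genes or reads, removal of the length trend and random lists of genes with a symbol were chosen after the data had been seen; the other settings here were planned. Of 541 recomputed list positions, 524 stayed on the same side of the limits. With list means in place of medians, 4 lists in place of 2 lay above: Wnt targets at 0.25 and p53 genes at 0.47 joined, while Notch (-0.88), endothelial (-1.10) and pericyte and adipocyte genes (-0.77) came to lie below, and Hedgehog genes (-0.53) came to lie inside. Without the most extreme member, 1 list lay above, as muscle (0.50), and Hedgehog (-0.84) and heat shock genes (-0.19) came to lie inside. With no filter on low values 1 list lay above (muscle 0.12, inside) and pericyte and adipocyte genes lay below at -0.61; with an FPKM of at least 5, 1 list lay above and the latter lay at -1.65. A pseudocount of 0.1 put endothelial genes below at -1.53. BMP and TGF-beta genes came to lie inside after the median-ratio (-0.37) and trimmed-mean scalings (-0.36). Matching on length brought extracellular matrix (-0.37) and heat shock genes (-0.45) inside. Scaling to equal FPKM totals gave 3210 genes lower, over 1.5 times the 2138 reported. It also raised FPKM values against the fixed added 1 and filter, and measured 14150 genes in place of 13163. How much of that move is due to scaling between the libraries was not tested, nor was the cause of the other moves. Counts of higher and lower list members that moved under a scaling by over 1.5 times and by more than 1 gene stand beside each list. Taking 1 row per symbol moved nothing, since no symbol was repeated. For 182 genes, 1322 of 1983 recomputed ratios lay within the counting interval or were unchanged, and 661 lay outside. The ratios hold an added constant that the interval lacks. These counts therefore do not show how many ratios a setting moved beyond counting error. Of the 115 among those 182 genes that were at least 2-fold higher or lower, 25 lost that place in at least 1 setting. CCND1, DHX58, ENO1, FZD7, SRSF3 and TNC did so after the median-ratio and trimmed-mean scalings, all but CCND1 and DHX58 also with mitochondrial reads left out of the totals, and NDUFB3 and AXIN1 at equal FPKM totals. AXIN1 did so too when the mitochondrial or the 20 most abundant genes were removed first, and FGF19 with the former removal. The filters on low values took out 18 (FPKM of at least 5) and 5 (mean FPKM of at least 1). Removing the length trend with the overall median kept gave 884 genes higher and 2132 lower, and cannot show what length does to that balance. FGF20 has 0 and 1 reads at any setting, under the floor of 3 reads, and an incomplete gene model was not excluded. No paired analysis was possible because each group had 1 library, and no library could be left out.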

Other observations

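The tests in this part were chosen after the data had been seen, the KEGG pathways included, apart from the planned scalings; the bounds for gene length in the cell cycle genes were set before that test's result. Pathways of the table's own KEGG annotation, most disease maps left out, were compared with random lists drawn from the 4893 measured genes with a pathway, whose median log2 ratio was -0.18. Of 223 pathways with at least 20 measured genes, 16 stood above and 75 below the central 95%, where 11.15 would by chance. These random lists were matched on expression and not on gene length. Across 10 groups of measured genes by length, the median log2 ratio was 0.14 in the shortest and -0.40 in the longest. What length adds to the pathway positions was not tested. Pathways share many genes and are not independent. The ribosome biogenesis pathway, which makes and assembles ribosomal RNA, had 24 of 73 genes at least 2-fold higher and 0 lower, with a median of 0.73 at percentile 100. RNA polymerase subunits had 8 of 31 higher and 4 lower, with a median of 0.48, and aminoacyl-tRNA synthesis had 5 of 48 higher and 2 lower, with a median of 0.21. The spliceosome pathway had 8 of 133 higher and 7 lower, with a median of 0.31 at percentile 100, above the random lists, whereas the 28 spliceosome genes listed beforehand lay inside them. Oxidative phosphorylation had 13 of 116 higher and 2 lower, with a median of 0.48 at percentile 100, whereas the 25 nuclear respiratory genes listed beforehand lay inside the random lists. Without its 13 mitochondrially encoded genes the pathway had 11 of 103 higher and 2 lower, with a median of 0.43.

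On the lower side, adherens junctions had 25 of 73 genes at least 2-fold lower and 2 higher, with a median of -0.70, and tight junctions had 32 of 128 lower and 4 higher, with a median of -0.60. Axon guidance, which holds semaphorins, ephrins and their receptors, had 53 of 160 lower and 5 higher, with a median of -0.69. As for the pathways above, gene length was not matched for any of the lower ones. Regulation of the actin cytoskeleton had 51 of 194 lower and 10 higher (-0.63), focal adhesion 47 of 167 and 7 (-0.57), the Hippo pathway 29 of 123 and 9 (-0.53) and DNA replication 15 of 35 and 0 (-0.92), all at percentile 0. The KEGG Wnt pathway had 13 of 120 higher and 26 lower, with a median of -0.25 at percentile 45.0, inside the random lists. The KEGG Hedgehog pathway had 1 of 36 higher and 7 lower, with a median of -0.14 at percentile 54.1, inside the random lists, whereas the 10 Hedgehog genes listed beforehand lay below them.

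DNA replication and mitosis genes were lower in the SKL2001 library. Scaling does not account for it, since the median of both lists was -1.63 in the scaling that brought it closest to 0, and gene length does not either, since the median lay at percentile 0 of lists matched on expression and length. A p53 response is a candidate explanation that stays open, since 8 of 20 members of its list were higher and 1 lower, and the list lay at percentile 69.8 by its median but 99.88 by its mean. The KEGG p53 pathway had 10 of 59 genes higher and 13 lower at percentile 70.5, and KEGG apoptosis had 14 of 131 higher and 28 lower at percentile 0.44. Whether these pathways hold genes of the cell cycle lists was not examined, so their positions cannot weigh on a p53 response. Cultures that differ in growth state or density may show the same genes without the compound, and with 1 library per group the effect of SKL2001 and such a difference cannot be told apart.

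More genes were lower than higher in the SKL2001 library. With mitochondrial reads left out of the library totals, 62.6% of the differing genes were lower in place of 68.7%. The larger share of those reads is thus not the whole cause but may be part of it. With the mitochondrial genes removed before the FPKM totals were made equal 74.6% were lower, and with them at equal totals 78.4% were. Those settings used different common totals and had 13153 and 14150 measured genes, so removal of mitochondrial genes is not all that differs. Gene length stays open, since 58.6% of the differing genes at or below the median length were lower and 79.4% of those above it. Scaling stays open too, since the share lower was 56.6% after the trimmed mean and 58.1% after the median ratio. It was 78.4% at equal FPKM totals and 74.4% when the 20 most abundant genes were removed first. At equal FPKM totals the values also rose against the fixed added 1 and filter, so 78.4% does not show scaling alone. Which scaling is right cannot be settled from these libraries.

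Wnt targets were found on both sides, with 7 of 25 members higher and 5 lower. Scaling does not account for this, since the scalings tried gave at least 7 members higher and at least 3 lower. Low genes are among these members: a filter at an FPKM of at least 5 took out T on the lower side and DKK4 on the higher. A response of part of the list to SKL2001 and a difference between the cultures other than the compound cannot be told apart, since each group had 1 library and the counting intervals leave out the spread between cultures.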
